A study of Glycine max with 12 samples.

How the data were processed

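Leaf mRNA of the soybean cultivar HN95 was measured by RNA sequencing in 12 libraries that the labels place in 4 groups of 3. All plants were under saline-alkali stress, imposed with a mixed salt solution (the sulfate and hydrogen carbonate of sodium at 320 mM each, its chloride and carbonate at 40 mM each). Whether control plants were sprayed with water is not stated. The groups were a stressed control, a foliar spray of 200 mg/L nano-SiO2, a foliar spray of 300 µM melatonin (MT), and a spray with both, and leaves were taken 7 days after spraying. Per the labels' protocols, polyadenylated RNA was enriched with oligo(dT) beads and cut to fragments of about 200 bp before cDNA synthesis and PCR. All 12 libraries carry 1 and the same batch label, so no batch could be compared with another.

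The authors deposited 1 FPKM value (fragments scaled by transcript length and library size) per gene and library, per the file headers. The aligner, the quantifier and the strand setting are not given in the sources used here. The gene identifiers belong to the annotation Wm82.a4.v1 of the Williams 82 reference, and this suffix is left out of the identifiers in the text. The authors' deposited table also has a p-value and a q-value per gene from a test whose comparison the table does not name, so these columns were only described. The submitters' processing notes name DESeq2 1.34.0 and R 4.1.2. Read counts were not used here, and the tests planned for counts were therefore replaced by those planned for FPKM. Of 46446 genes, 606 were listed at 0 in every library and 45546 (98.1%) had a description, which served as the gene name. None of the identifiers matched the RefSeq table for assembly Glycine_max_v4.0 with 59048 genes (0 matched), so no coordinates are given beyond the chromosome number held in the identifier. Where an identifier reads 01G124500, the gene lies on chromosome 1.

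Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, which left 28260. Fold changes are differences on this log2 scale, which understates changes of genes with low FPKM. All 12 libraries entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend and robust settings), so each comparison borrowed the spread of all groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The 6 contrasts were each spray against control, the combined spray against each single spray, and the interaction, defined as the MT effect in the presence of nano-SiO2 minus the MT effect in its absence. An F test asked whether a gene differed among the 4 groups at all. Because the labels call the libraries biological replicates without saying that they came from separate plants or pots, the p-values measure the spread between these samples, which may be partly technical.

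The comparisons, the filter, 38 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. A gene belonged to a list if any entry of its description matched the search words of that list and no excluded word. Of the 38 lists, 37 had at least 5 tested members and were tested with limma's camera at an inter-gene correlation of 0.01, with adjustment over the lists; the list of root and nodule genes had too few members. Camera compares a list with all other genes, so a list can move relative to them while its own median lies near 0. The test was repeated with a correlation estimated for each list, under which none of the lists passed in any comparison. Genes were named by 3 criteria per comparison: the 6 largest rises and 6 largest falls among called genes of at least 5 FPKM in the higher group whose libraries did not overlap; up to 2 called members of each of up to 10 lists; and the most abundant member of a list that passed without a called member. The text gives values for part of the genes under this rule, mostly those whose calls held in every fit with 1 library left out, and names the exceptions.

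Depth is not stated in FPKM, but the step between low values of 1 gene gave the relative depth of the libraries, 0.85 to 1.27 around their mean, with a largest disagreement of 0.004 on the log2 scale. Absolute depth, and with it the counting error of each value, is unknown. Members of gene families with close copies, such as ferritins, vegetative storage proteins, superoxide dismutases and asparagine synthetases, can share reads, and how the authors divided such reads is not given in the sources used here.

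The workflow was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 28260. Recovery was 90% and 97% for nano-SiO2 against control, 87% and 98% for MT against control, 89% and 98% for the combined spray against control, 85% and 99% for the combined spray against nano-SiO2, and 88% and 97% for the combined spray against MT. The interaction recovered 59% and 96%, and the F test 90% and 98%. Of the calls, between 2.1% and 6.6% were false. The simulated noise was normal and independent between genes, and only genes above a set mean level were changed. In the real libraries 1 shared axis held 39.2% of the variance within groups, and some named genes have low FPKM. The simulated shares may therefore not hold for them.

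Alternatives were the replicate number as a block, quantile normalization, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, eBayes without trend and robust settings, an absolute log2 change of at least 1, only the 2 groups compared in the fit, an estimated correlation for the lists, and each library left out in turn. Median-ratio scaling, the joint removal of control 1 and nano-SiO2 2, and the comparison of nano-SiO2 with MT were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.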

Results

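Expression in leaves of stressed soybean was compared 7 days after spraying with nano-SiO2 (silica nanoparticles, 200 mg/L), melatonin (MT, an indoleamine also made by plants, 300 µM) or both, with 3 libraries per group and 3 libraries of the stressed control. The title of the series concerns nano-SiO2 as a carrier of melatonin and its relation to photosynthetic carbon metabolism and yield. Summed FPKM per library ranged from 522120 to 559092, and between 25557 and 27660 genes per library reached 1 FPKM. The 20 most abundant genes held between 9.501% of the summed FPKM (nano-SiO2 2) and 18.04% (control 1). Values are mean FPKM ± SD with n = 3 libraries per group, log2 changes refer to FPKM + 1, and adjusted p-values are from limma. In these comparisons, called genes given with values kept the call in every fit with 1 library left out that tested them, unless the text says otherwise.

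Differences between group means held 43.9% of the variance of the tested genes. This share is not adjusted for the number of groups and would be positive even if the sprays changed nothing. The first 3 principal components held 32.9%, 19.1% and 14.2%, and libraries of 1 group lay apart on the first of them. Control 1 (-27.8, against 17.2 and 24.7) and MT 3 (8, against -26.6 and -30.1) were farthest from the others of their groups. Correlations between libraries of the same group ran from 0.958 to 0.992. Over the 4 groups, 1164 genes differed by the F test. That number was 484, 606, 560, 675 and 745 without control 2, control 3, MT 1, MT 2 and nano-SiO2+MT 1, and 632 without control 1 and nano-SiO2 2 together.

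**Figure D1:**
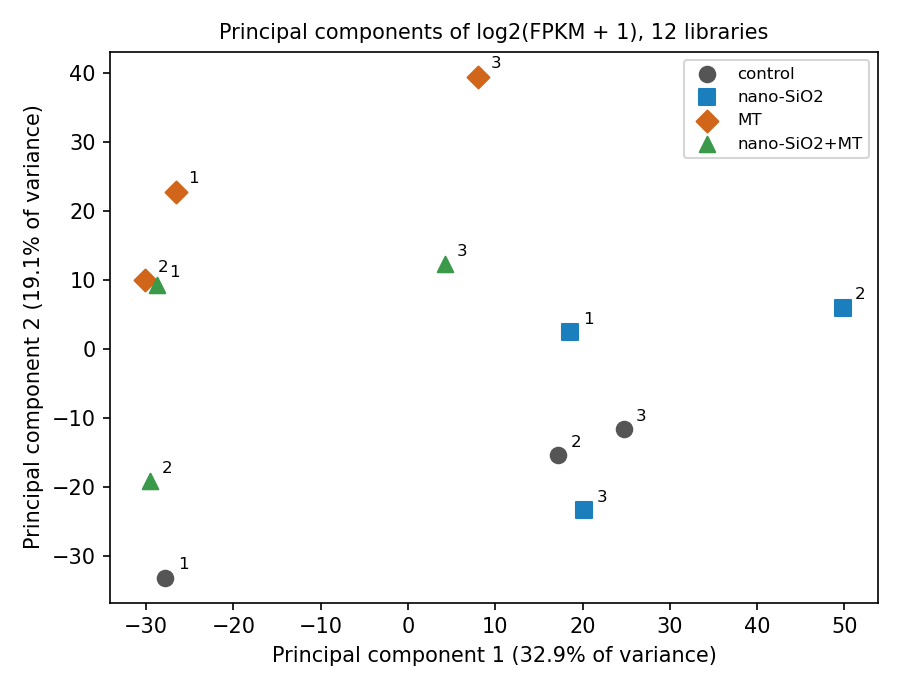
Principal components 1 and 2 (32.9% and 19.1% of the variance) of log2(FPKM + 1) over the tested genes, with 1 point per library, marked by group and replicate number. Libraries of the same group spread widely along the first component.

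**Figure D2:**
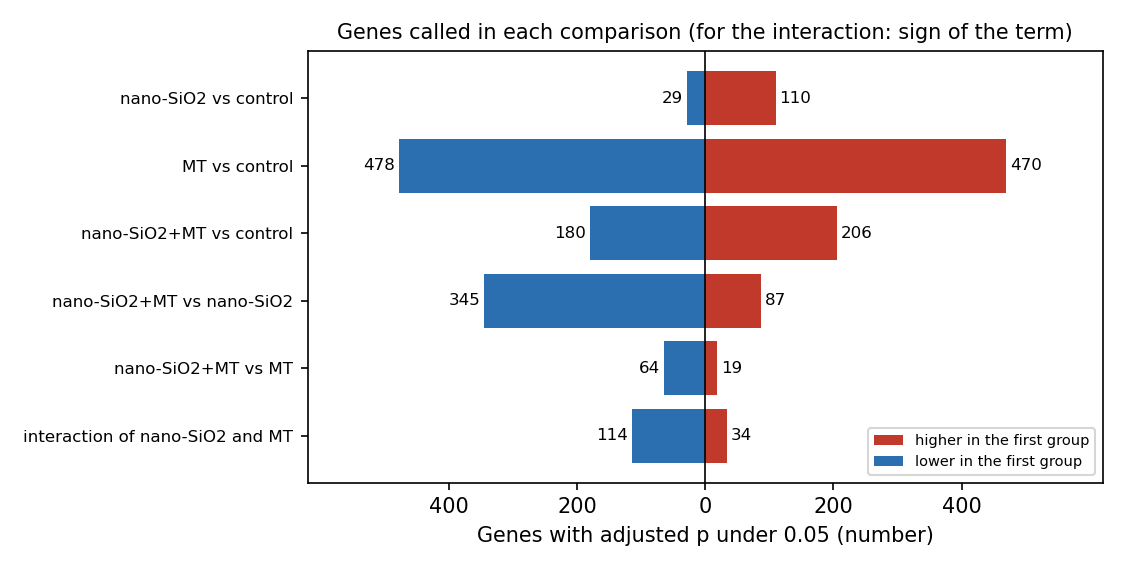
Number of genes with an adjusted p under 0.05 (limma) in each comparison, higher to the right and lower to the left; for the interaction the side is the sign of the term. MT against control has the most genes and nano-SiO2+MT against MT the fewest.

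Nano-SiO2 against control asks which genes differ with the particles alone. Of 8 tested ferritin genes, which encode proteins that store iron, 5 were called lower, and of 5 iron superoxide dismutase genes 2 were called higher (counts chosen after the values were seen). Ferritin-2 (Glyma.01G124500) went from 97.2 ± 10.1 to 16.9 ± 2.79 FPKM (log2 change -2.47, SE 0.15, adjusted p = 2.13e-06). Glyma.03G050100, Glyma.18G205800 and Glyma.07G155200 fell by 2.42, 2.18 and 1.94. A chloroplast iron superoxide dismutase, an enzyme that removes superoxide (Glyma.20G196900), rose from 0.436 ± 0.121 to 23.7 ± 2.78 FPKM (log2 change 4.1, SE 0.21, adjusted p = 4.06e-07). Its relative Glyma.10G193500 rose from 0.0433 ± 0.0377 to 4.25 ± 1.2 FPKM. Of 5 genes of vegetative storage proteins, described as stem 31 kDa glycoproteins and known to store nitrogen in soybean leaves, 2 rose as well. Glyma.07G014500 went from 5.74 ± 0.824 to 148 ± 35.5 FPKM (log2 change 4.44, SE 0.21, adjusted p = 4.06e-07) and Glyma.08G200100 from 0.159 ± 0.0307 to 18.4 ± 2.54 FPKM (log2 change 4.06). A ruBisCO-associated protein (Glyma.01G142400) rose from 5.73 ± 1.12 to 107 ± 19.6 FPKM (log2 change 4.01, adjusted p = 4.06e-07). A beta-amylase, an enzyme of starch breakdown (Glyma.06G301500), rose from 26 ± 3.29 to 78.3 ± 15 FPKM (log2 change 1.55, adjusted p = 6e-04).

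**Figure D3:**
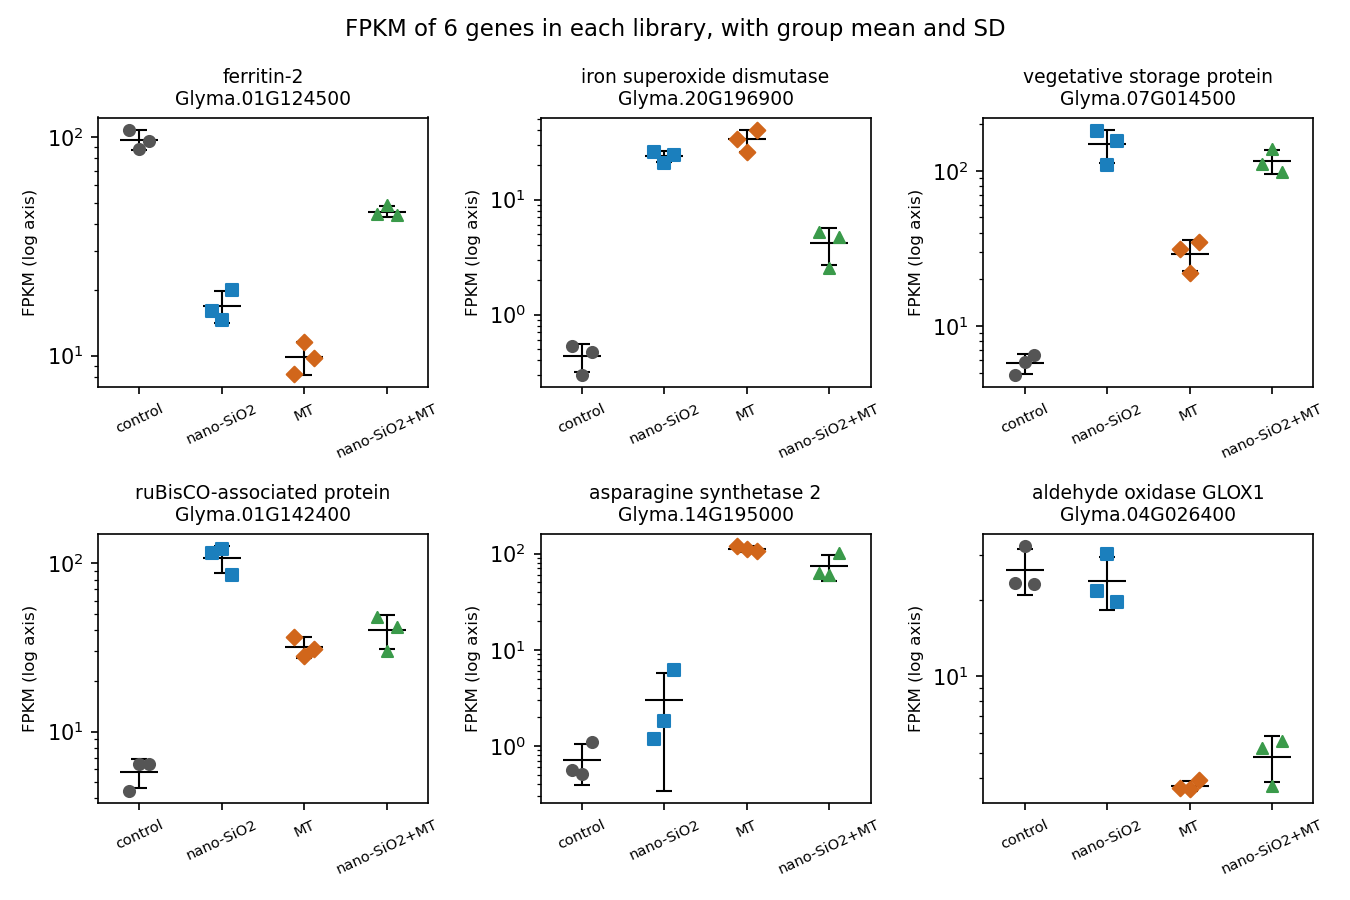
FPKM on a log axis of 6 genes in each library by group (points), with the group mean (horizontal mark) and SD (bars, n = 3). Ferritin-2 is lowest and the iron superoxide dismutase highest in the single sprays, whereas asparagine synthetase 2 and GLOX1 separate the groups with MT from those without it.

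Among 51 jasmonate synthesis and JAZ genes, 8 were called higher, 1 lower and 42 did not pass, and 19 higher and 3 lower passed when adjusted over the list alone. A lipoxygenase, an enzyme that oxidises linoleic and linolenic acid (Glyma.13G347800), rose from 0.751 ± 0.459 to 5.49 ± 0.663 FPKM (log2 change 1.92). The gene described as jasmonic acid-amido synthetase JAR1 (Glyma.15G241600) fell from 1.98 ± 0.244 to 0.217 ± 0.103 FPKM (log2 change -1.29, adjusted p = 0.000603; 0.0524 with a pseudocount of 0.1). This list stood above the other genes (median log2 change 0.26, camera adjusted p = 2.2e-05; adjusted p = 0.598 with an estimated correlation). Of 5 vegetative storage protein genes, 2 rose, also when adjusted over the list alone (2 higher), and the list passed (median 0.41, mean 1.78, camera adjusted p = 1.02e-05; adjusted p = 0.198 with an estimated correlation).

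The light-harvesting antenna list lay lower (35 genes, median -0.22, camera adjusted p = 1.16e-13; adjusted p = 0.367 with an estimated correlation), with 1 gene called lower and 3 lower when adjusted over the list alone. The 43 chlorophyll synthesis genes (median -0.16, camera adjusted p = 1.07e-12; adjusted p = 0.17 with an estimated correlation) held no called gene and 6 lower when adjusted over the list alone. The 258 cytosolic ribosomal protein genes had a median of -0.20 (camera adjusted p = 9.84e-24; adjusted p = 0.522 with an estimated correlation), with 0 called over all genes or over the list alone. Photosystem and electron transport subunits also lay lower (67 genes, median -0.15, camera adjusted p = 9.29e-11; adjusted p = 0.198 with an estimated correlation), with 0 called by either adjustment. Plastocyanin (Glyma.04G020300), an electron carrier, had 1800 ± 164 FPKM against 2350 ± 573 in control and did not pass (adjusted p = 0.495). Without control 1 and nano-SiO2 2, the antenna and photosystem lists no longer passed (adjusted p = 0.0675 and 0.0502). The Calvin cycle list passed at 0.0257 with a median of -0.02 (adjusted p = 0.82 with an estimated correlation) but not without control 1 (0.787), nano-SiO2 1 (0.0553) or nano-SiO2 2 (0.348). It held 0 called genes by either adjustment. Relative to all genes it turned from -0.12 to 0.01 under quantile normalization and to 0.06 without control 1 and nano-SiO2 2, and with no filter on low values its adjusted p was 0.0775.

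Among markers of other cell types and organs, the 22 xylem and secondary wall genes had a median of 0.56 (camera adjusted p = 0.000656; adjusted p = 0.82 with an estimated correlation), with 0 called by either adjustment and no pass without nano-SiO2 3 (0.262). Dividing-cell genes had a median of -0.02 (57 genes, camera adjusted p = 0.00053; adjusted p = 0.598 with an estimated correlation), with 0 called by either adjustment. They did not pass without nano-SiO2 2 (0.177) or without control 1 and nano-SiO2 2 (0.14). Of 15 seed and pod genes, 2 were higher and 1 lower, the latter a Kunitz trypsin inhibitor (Glyma.08G341700) that fell from 10.4 ± 2.54 to 2.15 ± 0.421 FPKM (log2 change -1.84). When adjusted over the list alone, 3 seed and pod genes were higher and 3 lower.

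In all, 139 genes were called in nano-SiO2 against control, 110 higher and 29 lower, around a median log2 change of 0.098 over all genes, and 14 lists passed, 6 up and 8 down. Genes called lower numbered 57 and 60 without nano-SiO2+MT 2 and nano-SiO2+MT 3 (65.5% and 65.3% higher) and 59 with only these 2 groups in the fit (58.7% higher). The number of genes was 51, 43, 63, 78 and 54 without control 1, control 2, control 3, nano-SiO2 1 and nano-SiO2 2, and 29 without control 1 and nano-SiO2 2 together, all of them among the 139. It was 69 with a mean of at least 5 FPKM and 91 with an absolute log2 change of at least 1.

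MT against control asks which genes differ with melatonin alone. Genes of asparagine synthetase, which moves nitrogen from glutamine to asparagine, rose strongly in 3 cases. Asparagine synthetase 2 (Glyma.14G195000) went from 0.718 ± 0.322 to 112 ± 7.16 FPKM (log2 change 6.05, SE 0.35, adjusted p = 1.37e-06). An asparagine synthetase-like gene (Glyma.02G228100) rose from 1.04 ± 0.25 to 123 ± 14.7 FPKM (log2 change 5.93, SE 0.23, adjusted p = 4.34e-08), and Glyma.11G171400 from 0.00445 ± 0.00771 to 9.08 ± 0.782 FPKM (log2 change 3.32). Iron superoxide dismutase Glyma.20G196900 rose to 33.2 ± 7.13 FPKM (log2 change 4.56, adjusted p = 1.43e-07). Ferritin-2 Glyma.01G124500 fell to 9.85 ± 1.67 FPKM (log2 change -3.19, adjusted p = 1.43e-07), with the ferritin genes Glyma.18G205800, Glyma.03G050100 and Glyma.07G155200 down by -2.91, -2.89 and -2.82. A gene described as aldehyde oxidase GLOX1 (Glyma.04G026400) fell from 26.3 ± 5.41 to 3.71 ± 0.166 FPKM (log2 change -2.52, SE 0.18, adjusted p = 6.58e-06). A purple acid phosphatase (Glyma.08G056400) rose from 0.662 ± 0.118 to 7.55 ± 0.98 FPKM (log2 change 2.36, adjusted p = 5.3e-05).

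Of 91 nitrogen assimilation genes, 10 were called higher, 1 lower and 80 did not pass, and 12 higher and 2 lower passed when adjusted over the list alone. The median was -0.02, the mean 0.21, and the test pointed up (camera adjusted p = 0.0112; adjusted p = 0.932 with an estimated correlation). It no longer passed without control 1 (0.13), without control 1 and nano-SiO2 2 (0.128) or with no filter on low values (0.0711). The 72 phenylpropanoid and lignin genes held 10 called lower and none higher, or 29 lower and 2 higher when adjusted over the list alone (median -0.35, camera adjusted p = 2.94e-07; adjusted p = 0.471 with an estimated correlation). Among them, phenylalanine ammonia-lyase 2, which starts the pathway (Glyma.10G209800), fell from 3.82 ± 0.311 to 1.64 ± 0.0876 FPKM (log2 change -0.87, adjusted p = 0.00271). Laccase-12, of a family that polymerises lignin (Glyma.11G233400), fell from 5.98 ± 0.422 to 0.942 ± 0.194 FPKM (log2 change -1.85, adjusted p = 0.00398). Class III peroxidases followed, with 5 of 30 called lower, 11 lower and 1 higher when adjusted over the list alone, and a median of -0.33 (camera adjusted p = 0.000407; adjusted p = 0.471 with an estimated correlation; 0.0875 with no filter on low values). Peroxidase 22 (Glyma.09G022400) fell from 4.52 ± 0.357 to 1.76 ± 0.199 FPKM (log2 change -1.0). Chalcone synthase 2, the first enzyme of flavonoid synthesis (Glyma.06G118550), fell from 46.4 ± 3.16 to 22.6 ± 3.04 FPKM (log2 change -1.01, adjusted p = 0.00172). Of 78 flavonoid genes 6 were lower, and 10 when adjusted over the list alone, and that list did not pass (camera adjusted p = 0.329).

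Xylem and secondary wall markers were lower beside the phenylpropanoid genes: 5 of 22 were called lower, and 15 when adjusted over the list alone (median -0.99, camera adjusted p = 1.52e-07; adjusted p = 0.525 with an estimated correlation). Fasciclin-like arabinogalactan protein 11 (Glyma.03G180000), of developing secondary walls, fell from 6.19 ± 1.39 to 1.48 ± 0.233 FPKM (log2 change -1.52, adjusted p = 0.0038). Ethylene synthesis and ERF genes lay higher, with 8 called higher and 3 lower of 89, and 14 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.00287; adjusted p = 0.471 with an estimated correlation; 0.121 without MT 2). The factor ERF106 (Glyma.20G070100) rose from 9.11 ± 0.323 to 26.9 ± 3.93 FPKM (log2 change 1.46, adjusted p = 0.000521). Of 27 chlorophyll breakdown and senescence genes, 5 were higher, with 8 higher and 3 lower when adjusted over the list alone (median 0.13, camera adjusted p = 0.00183; adjusted p = 0.471 with an estimated correlation; 0.0987 without MT 1). Of 50 genes of reactive oxygen scavenging, 2 were higher, both of them among the 5 iron superoxide dismutases, and 2 lower, with 4 higher and 5 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.239).

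The photosynthesis lists moved little with MT. Antenna genes had a median of 0.01 and a mean of -0.09, with the test downward (3 lower by either adjustment, camera adjusted p = 0.894). Calvin cycle genes had a median of -0.01 and a mean of 0.01, with the test upward (0 called by either adjustment, camera adjusted p = 0.269). Photosystem subunits had a median of 0.01 and a mean of 0.08 (1 higher and 1 lower by either adjustment, camera adjusted p = 0.0495; adjusted p = 0.893 with an estimated correlation). That list did not pass without control 2 (0.349), control 3 (0.612) or MT 1 (0.504), with the replicate number as a block (0.0513) or with no filter (0.0501), and turned from 0.05 to -0.06 relative to all genes under quantile normalization. Chlorophyll synthesis genes had a median of -0.20, with 3 lower and 1 higher, or 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.471 with an estimated correlation; 0.304 and 0.113 without control 1 and MT 3, and 0.264 without control 1 and nano-SiO2 2). Uroporphyrinogen-III C-methyltransferase, which leads to sirohaem rather than chlorophyll (Glyma.08G150800), was the member called higher, from 4.43 ± 0.413 to 12.2 ± 2.05 FPKM (log2 change 1.28, adjusted p = 0.000135). Cytosolic ribosomal protein genes had a median of -0.26 (2 of 258 lower, 0 when adjusted over the list alone; camera adjusted p = 1.52e-07; adjusted p = 0.867 with an estimated correlation). Seed and pod genes were higher, 4 of 15 by either adjustment (median 0.26, camera adjusted p = 0.000422; adjusted p = 0.471 with an estimated correlation). Of 5 vegetative storage protein genes 2 were higher by either adjustment (camera adjusted p = 0.00141; adjusted p = 0.471 with an estimated correlation; 0.162 with no filter).

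Together, 948 genes were called in MT against control, 470 higher and the others lower (median over all genes -0.049), and 12 lists passed, 6 up and 6 down. The number of genes was 350, 391, 389 and 477 without control 2, control 3, MT 1 and MT 2. It was 603 with a mean of at least 5 FPKM and 296 with an absolute log2 change of at least 1, of which 180 were higher and 116 lower. The share called higher was 59.6% under median-ratio scaling (680 higher, 461 lower), 57% under quantile normalization, 65.7% without control 2 or control 3 and 62.5% without MT 1, against 49.6% with all libraries, and 42% with the replicate number as a block. Evening clock genes, chosen after the results had been seen, were lower with MT in 10 of 10 cases (mean -0.35, SE 0.13 over libraries). Their mean was also lower with both sprays (-0.43, SE 0.13) but near control with nano-SiO2 (-0.02, SE 0.13). Of these 10 genes 1 was called with MT. The 3 morning clock genes had medians of 0.19 with MT, 0.01 with both sprays and 0.12 with nano-SiO2, and 0 were called with MT. A different hour of sampling was weighed only for the ferritin and iron superoxide dismutase genes. For the other genes that differed with MT it stays open.

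The combined spray against control asks what nano-SiO2 and MT do together. Asparagine synthetase 2 (Glyma.14G195000) rose to 74.5 ± 22.2 FPKM (log2 change 5.43, SE 0.35, adjusted p = 1.78e-05) and Glyma.02G228100 to 71 ± 20 FPKM (log2 change 5.12, adjusted p = 2.8e-07). Of 5 vegetative storage protein genes 2 rose, Glyma.07G014500 to 116 ± 20.5 FPKM (log2 change 4.11, adjusted p = 6.9e-07) and Glyma.08G200100 to 12.2 ± 3.06 FPKM (log2 change 3.49). So did the ruBisCO-associated protein Glyma.01G142400 (40.1 ± 9.11 FPKM, log2 change 2.60, adjusted p = 3.2e-05). The large subunit of glucose-1-phosphate adenylyltransferase, which commits carbon to starch (Glyma.11G116600), rose from 6.07 ± 0.462 to 26 ± 5.11 FPKM (log2 change 1.92, adjusted p = 0.000364). GLOX1 (Glyma.04G026400) fell to 4.84 ± 1 FPKM (log2 change -2.23, adjusted p = 6.43e-05). SMAX1-LIKE 6, of strigolactone signalling (Glyma.18G062300), fell from 10.2 ± 0.413 to 4.08 ± 0.345 FPKM (log2 change -1.14), and expansin-A4, which loosens cell walls (Glyma.07G132600), from 10.8 ± 1.86 to 3.61 ± 0.825 FPKM (log2 change -1.35).

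Of 91 nitrogen assimilation genes 7 were higher and none lower, or 8 higher and 1 lower when adjusted over the list alone. The median of -0.12 and the mean of 0.12 differed in sign, and the list did not pass (camera adjusted p = 0.167). Phenylpropanoid and lignin genes lay lower, with 2 of 72 called lower and 9 when adjusted over the list alone (median -0.29, camera adjusted p = 5.28e-06; adjusted p = 0.738 with an estimated correlation). Beside them, xylem and secondary wall genes had a median of -0.61 with 1 called lower by either adjustment and did not pass (camera adjusted p = 0.0985), but passed with the replicate number as a block (0.00624). Circadian clock genes lay lower, with 1 of 47 called lower and 8 when adjusted over the list alone (median -0.16, camera adjusted p = 0.00212; adjusted p = 0.918 with an estimated correlation). Abscisic acid genes lay higher (34 genes, 1 called higher, 2 higher and 2 lower when adjusted over the list alone; median 0.17, camera adjusted p = 0.007; adjusted p = 0.166 with an estimated correlation; 0.126 with no filter). Of the sodium, potassium and proton transport genes, the chloride channel CLC-b (Glyma.16G057600) rose from 0.694 ± 0.224 to 2.65 ± 0.713 FPKM (log2 change 1.10, adjusted p = 0.00496). Antenna, photosystem and Calvin cycle genes had medians of 0.06, 0.06 and -0.01 and did not pass (camera adjusted p = 0.457, 0.131 and 0.167). The means of antenna and Calvin cycle genes differed in sign from their medians (-0.02 and 0.02). None was called, and 3 antenna genes were lower when adjusted over the list alone.

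A total of 386 genes were called in the combined spray against control, 206 higher and 180 lower (53.4% higher; 65.3% of 441 under median-ratio scaling), and 8 lists passed, 2 up and 6 down. That number of lists does not set the real grouping apart. Of 10 splits of these libraries, 8 reached it, and the highest other had 15 lists. Leaving out control 2, control 3, nano-SiO2+MT 1 or nano-SiO2+MT 3 gave 60, 108, 109 or 111 genes (76.7%, 74.1%, 71.6% and 64.9% higher), and without nano-SiO2+MT 3 the number of lists was 14. With no filter on low values 239 genes were called, and 113 had an absolute log2 change of at least 1.

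The 3 responses share the control libraries, so they resemble each other by construction. Fold changes of nano-SiO2 and MT correlated with r = 0.43 across genes, nano-SiO2 and the combined spray with 0.41, and MT and the combined spray with 0.74, against 0.50 simulated for unchanged groups. Genes are not independent replicates. The covariances were 0.0362, 0.0286 and 0.0635, against 0.0176, 0.0177 and 0.0177 simulated. The simulated noise was independent between genes. The simulated values therefore do not show how far noise shared between genes in the control libraries could move a covariance. Nano-SiO2 and MT shared 54 genes called higher and 18 lower, where independent lists would share 1.83 and 0.491. Nano-SiO2 and the combined spray shared 25 and 12 (independent lists, 0.802 and 0.185), and MT and the combined spray 159 and 130 (3.43 and 3.04). Part of the excess may come from the shared controls, which are too few to divide. The 289 genes shared by MT and the combined spray became 52, 91, 152, 176, 92 and 98 without control 2, control 3, MT 1, MT 2, nano-SiO2+MT 1 and nano-SiO2+MT 3. The 72 shared by nano-SiO2 and MT became 31, 21, 30, 44, 33, 46, 37, 45 and 47 without control 1, control 2, control 3, nano-SiO2 1, nano-SiO2 2, nano-SiO2 3, MT 1, MT 2 and nano-SiO2+MT 1. The 37 shared by nano-SiO2 and the combined spray became 15, 10, 13, 20, 18 and 21 without control 1, control 2, control 3, nano-SiO2 2, nano-SiO2+MT 1 and nano-SiO2+MT 3, and the correlation of this pair fell as low as 0.22 with 1 library left out.

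The combined spray against nano-SiO2 asks what MT adds to the particles. Asparagine synthetase 2 (Glyma.14G195000) rose from 3.02 ± 2.68 to 74.5 ± 22.2 FPKM (log2 change 4.39, SE 0.35, adjusted p = 0.000317) and Glyma.02G228100 from 3.84 ± 1.67 to 71 ± 20 FPKM (log2 change 3.91, adjusted p = 8.03e-06). The iron superoxide dismutase Glyma.20G196900 fell from 23.7 ± 2.78 to 4.16 ± 1.44 FPKM (log2 change -2.30, adjusted p = 0.000367). GLOX1 (Glyma.04G026400) fell from 23.8 ± 5.63 to 4.84 ± 1 FPKM (log2 change -2.08), and the beta-amylase Glyma.06G301500 from 78.3 ± 15 to 32 ± 3.37 FPKM (log2 change -1.25, adjusted p = 0.00376). Lipoxygenase-10 (Glyma.08G189600) fell from 2.69 ± 0.519 to 0.431 ± 0.143 FPKM (log2 change -1.36, adjusted p = 0.00451). Cellulose synthase-like protein G1 (Glyma.06G324300) fell from 13.7 ± 3.51 to 3.34 ± 0.788 FPKM (log2 change -1.75). The Kunitz inhibitor genes Glyma.08G341700 and Glyma.08G341600 rose from 2.15 ± 0.421 to 11.5 ± 2.22 and from 5.59 ± 1.41 to 16.4 ± 1.43 FPKM.

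The median over all genes was -0.148, and list medians are given relative to it. Antenna genes lay 0.44 above it (camera adjusted p = 2.98e-14; adjusted p = 0.432 with an estimated correlation), photosystem subunits 0.32 (9.51e-14; adjusted p = 0.301 with an estimated correlation), and chlorophyll synthesis genes 0.14 (0.000782; adjusted p = 0.537 with an estimated correlation). None of the antenna or photosystem genes was called by either adjustment, and of the chlorophyll synthesis genes 1 was higher, or 3 when adjusted over the list alone. Calvin cycle genes lay 0.19 above (0.000301; adjusted p = 0.537 with an estimated correlation) with 0 called by either adjustment, and at -0.01 under quantile normalization. Jasmonate genes lay at -0.14 (5 of 51 called lower, 15 when adjusted over the list alone; camera adjusted p = 3.19e-05; adjusted p = 0.537 with an estimated correlation). Phenylpropanoid genes lay at -0.20 (4 of 72 lower, 21 when adjusted over the list alone; 0.000782; adjusted p = 0.638 with an estimated correlation; 0.0515 without nano-SiO2 3; 0.12 with no filter). Xylem and secondary wall genes, at -0.87, were 3 of 22 lower, 13 when adjusted over the list alone (9.94e-06; adjusted p = 0.638 with an estimated correlation; 0.311 with no filter). Of 78 flavonoid genes 7 were lower, and 24 lower and 3 higher when adjusted over the list alone, without a pass (0.22). Isoflavone reductase homolog 2 (Glyma.04G012300) fell from 61.4 ± 21.8 to 22.4 ± 5.27 FPKM (log2 change -1.39, adjusted p = 0.0115, and 0.0655 without nano-SiO2+MT 1).

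Of 432 genes called between the combined spray and nano-SiO2, 87 were higher and 345 lower, or 20.1% higher. Quantile normalization, which shifted the median of all genes by 0.146, gave 138 higher and 169 lower (45% higher), and median-ratio scaling, with a shift of 0.151, gave 142 and 167. With the replicate number as a block there were 789 genes, 119 higher and 670 lower. The share higher was 35.9% without nano-SiO2 2 and 30.9% without nano-SiO2+MT 3. The number of genes was 221, 260, 174, 103, 267, 104 and 189 without control 2, control 3, nano-SiO2 1, nano-SiO2 2, MT 1, nano-SiO2+MT 1 and nano-SiO2+MT 2. It was 119 without control 1 and nano-SiO2 2 together, 115 with only these 2 groups in the fit, 229 with no filter, 273 with a mean of at least 5 FPKM and 164 with an absolute log2 change of at least 1. In this comparison 16 lists passed, 10 up and 6 down relative to the other genes.

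The combined spray against MT asks what nano-SiO2 adds to melatonin. Of 8 ferritin genes, 4 were called higher with the particles. Glyma.01G124500 rose from 9.85 ± 1.67 to 45.6 ± 2.61 FPKM (log2 change 2.11, SE 0.15, adjusted p = 1.82e-05). Glyma.07G155200, Glyma.18G205800 and Glyma.03G050100 rose by 2.01, 1.92 and 1.88. Of 5 iron superoxide dismutases 2 fell, Glyma.20G196900 from 33.2 ± 7.13 to 4.16 ± 1.44 FPKM (log2 change -2.75, adjusted p = 3.45e-05) and Glyma.10G193500 from 5.38 ± 0.708 to 0.389 ± 0.281 FPKM (log2 change -2.22). Of 5 vegetative storage protein genes 2 rose, Glyma.07G014500 from 29.3 ± 6.61 to 116 ± 20.5 FPKM (log2 change 1.96, adjusted p = 0.000518) and Glyma.08G200100 from 2.79 ± 1.63 to 12.2 ± 3.06 FPKM (log2 change 1.86, adjusted p = 0.00415, and 0.0777 with only these 2 groups in the fit). Asparagine synthetase Glyma.11G171400 fell from 9.08 ± 0.782 to 2.66 ± 1.13 FPKM (log2 change -1.50, adjusted p = 0.00132). The ERF017 genes Glyma.09G072000 and Glyma.15G180000 fell from 2.82 ± 0.792 to 0.0218 ± 0.0189 and from 2.28 ± 0.632 to 0.092 ± 0.0251 FPKM.

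Xylem and secondary wall genes lay higher than with MT alone (median 0.47, 0 of 22 called by either adjustment, camera adjusted p = 5.67e-10; adjusted p = 0.942 with an estimated correlation). The vegetative storage protein list passed with a median of 0.01 and a mean of 0.74 (2 of 5 higher by either adjustment, camera adjusted p = 0.000739; adjusted p = 0.584 with an estimated correlation). The seed and pod list lay lower (2 of 15 called lower, 3 when adjusted over the list alone, median -0.31, camera adjusted p = 0.000739; adjusted p = 0.584 with an estimated correlation; 0.254 with no filter). Glutathione transferases lay lower (41 genes, 0 called by either adjustment, median -0.19, camera adjusted p = 1.75e-05; adjusted p = 0.942 with an estimated correlation; 0.0632 without MT 3). Antenna, photosystem and Calvin cycle genes did not pass (medians 0.07, -0.03 and 0.03, the last with a test downward; camera adjusted p = 0.162, 0.332 and 0.917), with 0 called by either adjustment.

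Fewer genes passed here than in the other pairs, 83 in all, with 19 higher and 64 lower, and 1296 at an unadjusted p under 0.05. There were 34, 42, 42, 52 and 48 without MT 1, MT 2, MT 3, nano-SiO2+MT 1 and nano-SiO2+MT 2, 40 with a mean of at least 5 FPKM, 55 with an absolute log2 change of at least 1 and 53 with only these 2 groups in the fit. The share higher was 22.9%, and 40.4% without nano-SiO2+MT 1. In this pair 8 lists passed, 4 up and 4 down, and 13, 5 and 13 without nano-SiO2+MT 1, nano-SiO2+MT 2 and nano-SiO2+MT 3. Of 10 splits of these libraries, 9 put at least 8 lists past the threshold, and the highest other had 19.

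The interaction asks whether the combined spray differed from the sum of the single sprays on the log2 scale. Large terms belonged to 6 iron genes: -6.86 for the iron superoxide dismutase Glyma.20G196900 (SE 0.29, adjusted p = 1.48e-07), -4.52 for Glyma.10G193500 (adjusted p = 1.25e-06), and 4.58, 4.31, 4.1 and 3.95 for the ferritins Glyma.01G124500 (adjusted p = 1.75e-07), Glyma.03G050100, Glyma.18G205800 and Glyma.07G155200. Ferritin-2 (Glyma.01G124500) was at 97.2 ± 10.1 FPKM in control, 16.9 ± 2.79 with nano-SiO2, 9.85 ± 1.67 with MT and 45.6 ± 2.61 with both. The ruBisCO-associated protein Glyma.01G142400 had a term of -3.70 (5.73 ± 1.12, 107 ± 19.6, 31.9 ± 4.41 and 40.1 ± 9.11 FPKM in the same order; adjusted p = 1.59e-05). The vegetative storage protein Glyma.07G014500 had one of -2.48 (adjusted p = 0.00105), and senescence-associated nodulin 1A (Glyma.07G209100) one of -2.09 (10.7 ± 0.425, 19.5 ± 3.3, 18.1 ± 3.2 and 6.81 ± 1.2 FPKM; adjusted p = 0.000574). Terms of -2.57 and -2.32 belonged to purple acid phosphatase 17 (Glyma.08G056400) and acid phosphatase ACP1 (Glyma.08G195100), which release phosphate.

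Among the lists, vegetative storage proteins (2 of 5 genes negative by either adjustment, median -0.53, camera adjusted p = 0.00129; adjusted p = 0.564 with an estimated correlation; 0.0838 with no filter) and jasmonate genes (2 negative and 1 positive of 51, 12 negative and 2 positive when adjusted over the list alone; median -0.32, 0.000101; adjusted p = 0.564 with an estimated correlation) had negative terms. Antenna genes had positive ones (0 of 35 called, 3 positive when adjusted over the list alone; median 0.30, 1.58e-10; adjusted p = 0.564 with an estimated correlation). Xylem and secondary wall genes did not pass (0 of 22 called by either adjustment, median -0.20, mean -0.02, test upward, 0.283).

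The interaction was called for 148 genes, 114 with a negative and 34 with a positive term, around a median of -0.101 that both scalings moved to near 0 by 0.100 and 0.101. There were 88 without control 2, 213 without nano-SiO2+MT 3 (90 positive and 123 negative), 71 without control 1 and nano-SiO2 2 together, and 82 with a mean of at least 5 FPKM. The interaction recovered 59% of simulated terms of 1, so smaller terms could be missed.

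The authors' deposited table lists 1537 genes with a q-value under 0.05 for a comparison it does not name. Of these, 1422 were tested here and 829 differed by the F test. Across the tested genes, the rank correlation of the deposited p-value with the statistic computed here was 0.91 over control, nano-SiO2 and nano-SiO2+MT, 0.77 over the 4 groups and 0.08 for nano-SiO2+MT against MT.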

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

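The tests of reads shared between copies, of the hour of sampling, of iron and copper supply, of a batch marked by the replicate number and of vein tissue with libraries as units were chosen only after the results had been seen, and the hour test uses clock genes whose search words were corrected afterwards. A result is listed here because the effect of MT differed between plants with and without nano-SiO2 by the interaction test of limma, which called 148 genes. In 2 of 100 assignments of the 12 libraries to groups as many genes were called, the real one and another with 273. These assignments mix libraries of all 4 groups, which also breaks up the effects of the single sprays. They therefore bear on any difference among the groups and cannot judge the interaction alone. The F test over the 4 groups called 1164 genes, which 1 of 100 assignments reached, and the highest other had 18.

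Each pair of groups allows 10 splits of its 6 libraries, which are too few for a share under 0.05. The real split called 139 genes in nano-SiO2 against control (highest other 0), 948 in MT against control (2), 386 in nano-SiO2+MT against control (2), 432 in nano-SiO2+MT against nano-SiO2 (26), 83 in nano-SiO2+MT against MT (1) and 893 in nano-SiO2 against MT (1), so in each pair 1 split reached the real number. For gene lists past the threshold, the real and highest other numbers in the 5 planned pairs were 14 and 14, 12 and 13, 8 and 15, 16 and 15, and 8 and 19, and 3, 3, 8, 1 and 9 splits reached the real number. Except in nano-SiO2+MT against nano-SiO2, other splits thus gave as many lists as the real grouping, so these numbers do not set it apart.

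Among iron genes the interaction terms were 4.58 (Glyma.01G124500), 4.31 (Glyma.03G050100), 4.1 (Glyma.18G205800) and 3.95 (Glyma.07G155200) for ferritins, and -6.86 (Glyma.20G196900) and -4.52 (Glyma.10G193500) for iron superoxide dismutases. The ruBisCO-associated protein Glyma.01G142400 had -3.70, purple acid phosphatase Glyma.08G056400 -2.57, the vegetative storage proteins Glyma.07G014500 and Glyma.08G200100 -2.48 and -2.20, and acid phosphatase Glyma.08G195100 -2.32. Lipoxygenase Glyma.13G347800 had -2.15, senescence-associated nodulin Glyma.07G209100 -2.09, ERF017 Glyma.09G072000 -2.05, asparagine synthetases Glyma.02G228100 and Glyma.11G171400 -2.01 and -1.51, isoflavone reductase Glyma.04G012300 -1.95, and JAR1 Glyma.15G241600 1.38. These kept the call in every fit with 1 library left out that tested them, and Glyma.08G200100 lost it without control 1 and nano-SiO2 2 together (adjusted p = 0.12). The JAR1 term cannot be told from a floor at 0. This gene was at 0.3275, 0.2007 and 0.1233 FPKM with nano-SiO2 and 0, 0 and 0.02832 with MT. It could hardly fall further with both sprays, so a positive term was nearly fixed in advance.

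The other terms lost the call in some of these fits. Expansin-A8 Glyma.18G054000 (4.42) and pectate lyase Glyma.17G126500 (3.52) kept it in 2 of 12, with highest adjusted p of 0.0985 without MT 2 and 0.105 without MT 3. Chalcone synthase 2 Glyma.06G118550 (1.08) kept it in 4, serine hydroxymethyltransferase 7 Glyma.04G254300 (-0.97) in 1 and chlorophyllase 2 Glyma.07G096900 (-1.01) in 2, with highest adjusted p of 0.107, 0.142 and 0.147, each without control 2. Beta-amylase Glyma.06G301500 (-1.30) kept it in 7, with 0.0757 without nano-SiO2+MT 1. ERF017 Glyma.15G180000 (-1.46) lost it without control 2 (0.0662) and nano-SiO2 2 (0.0625), and sucrose-phosphate synthase 4 Glyma.06G323700 (-1.49) without nano-SiO2 2 (0.0512) and MT 1 (0.0556).

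After each single spray 5 of 8 tested ferritin genes were called lower and 2 of 5 iron superoxide dismutase genes higher than in control, and after both sprays 4 and 1, while the most abundant ferritin, Glyma.11G232600, which like these counts was chosen after its values were seen, did not pass in either single spray (log2 change -0.08 with nano-SiO2, adjusted p = 0.808; -0.32 with MT, adjusted p = 0.213). Scaling is unlikely to produce this, since the smallest absolute log2 change of the 6 iron genes with the large interaction terms was 2.05 under quantile normalization, and so are reads moving between close copies, since the summed FPKM of all 9 ferritin genes changed by -1.21 with MT and -0.88 with nano-SiO2 (527 ± 40.2 in control, 228 ± 8.98 and 287 ± 20.6 FPKM, n = 3). A different hour of sampling is unlikely as the only cause. The mean of 10 evening clock genes was below control with MT (-0.35, SE 0.13 over libraries) and so was that of the 4 ferritins (-2.95, SE 0.11). With nano-SiO2 the evening genes lay near control (-0.02, SE 0.13) while these ferritins fell (-2.25, SE 0.11). With both sprays against MT the evening genes hardly differed (-0.07, SE 0.13) and the ferritins were higher (1.98, SE 0.11). With both sprays against nano-SiO2 the evening genes were lower (-0.41, SE 0.13) and these ferritins higher (1.28, SE 0.11). This last contrast weighs less, because its median over all genes was -0.148 and the evening genes were not rescaled. Plants of another haplotype stay possible: called genes formed 53 neighbouring pairs against 34.7 in 10000 draws (permutation p = 0.002), although only 1 of the 60 genes nearest these 6 was called (1.67% against 3.58%). Pairs were to share no word of their descriptions, but neighbours without an informative description also counted. Undescribed copies of 1 gene side by side can therefore add to the excess, and the random draws do not allow for them. The excess does not by itself speak for another haplotype. A change in iron and copper supply also stays possible, with 11 of 63 other iron and copper genes called in either spray (17.5% against 3.55%, odds ratio 5.75, Fisher exact p = 1.32e-05). All 11 were called with MT but 3 with nano-SiO2 (4.76% against 0.482%, Fisher exact p = 0.00373). The mean of 6 genes, the copper/zinc superoxide dismutases and their chaperone, was -0.70, -0.71 and -0.60 relative to control in the MT libraries. Of these 6 genes 2 were called lower with MT. With nano-SiO2 their mean was -0.12, 0.09 and -0.22, near the control libraries (0.13, -0.03 and -0.10). The 14 tested genes of other copper proteins and copper uptake had a median of 0.03 with MT, with 1 called higher and 0 lower.

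Libraries of the same group differed along 1 axis that held 39.2% of the variance within groups. Of 2 relations tested over the 12 libraries, the share of the 20 most abundant genes followed the axis (r = -0.95, permutation p = 3e-05, BH 6e-05; rho = -0.82, p = 0.002, BH 0.0039; r = -0.95 without the 2 libraries whose share was most extreme relative to their groups), so a few abundant genes may shape it. These 20 include ruBisCO small chain and antenna genes. Their share therefore cannot separate a few genes taking the signal from a joint change of photosynthesis genes. Relative depth did so less clearly (r = -0.42, p = 0.17, BH 0.17; rho = -0.56, p = 0.063, BH 0.063; r = -0.20 without the 2 libraries whose depth was most extreme relative to their groups), and the replicate number took 0.30 of the variance, so both stay open. Antenna genes had a median r with the axis of -0.81, against 0.36 over all genes. The highest medians were 0.66 for the 6 melatonin synthesis genes and 0.64 for the 47 circadian clock genes. The design gives no biological group along this axis, so no biological explanation was tested.

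Xylem and secondary wall genes were lower with MT than with nano-SiO2 (median -1.46, 22 of 22 lower, 15 called). A smaller share of veins in the sampled leaves might lower phloem markers too, but 29 of them had a median of -0.09 and the medians differed by 1.37. The phloem mean varied little over all libraries (2.05 to 2.25). Whether this list would register a change in vein share is not shown, so that explanation stays open. With libraries as units, the mean of phloem markers minus that of the xylem list differed by 1.4 (SE 0.33 from the spread within the 4 groups). Scaling is unlikely to account for the lower xylem values, since the xylem median was -1.30 under quantile normalization. Mean log2 values of the xylem list were 2.18, 2.59 and 2.74 in the control libraries and 1.53, 1.77 and 1.66 with MT. They were 2.58, 3.03 and 3.65 with nano-SiO2 and 1.59, 2.29 and 2.75 with both sprays. The difference between MT and nano-SiO2 may therefore join a fall with MT and a rise with nano-SiO2. An effect of MT, of nano-SiO2 or of each on secondary walls stays possible and was not tested apart.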

How the results depend on the processing

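Median-ratio scaling, the joint removal of control 1 and nano-SiO2 2, nano-SiO2 against MT and the left-out refits of its lists and of the interaction lists were chosen only after the data had been seen. Of 209 results for named genes, 179 were called, and 112 of these kept the call in every fit with 1 library left out that tested them, 103 in all 12 and 9 in only 9. Of 58 list results past the threshold in the 5 planned pairs, 27 stayed past it in all 12 fits, as did 8 of 13 for the interaction and 7 of 16 for nano-SiO2 against MT, and with an estimated correlation 0 lists passed in each of the 5 planned pairs. A left-out library leaves 2 in its group, and low counting depth, which is unknown in absolute terms, limits genes of low FPKM most. The cause of the changes below was not tested, except that a higher FPKM limit and a fold limit leave fewer genes.

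With a mean of at least 5 FPKM, the numbers of genes were 69 (nano-SiO2 against control), 603 (MT against control), 273 (nano-SiO2+MT against nano-SiO2), 40 (nano-SiO2+MT against MT), 82 (interaction), 446 (nano-SiO2 against MT) and 702 (F test). With an absolute log2 change of at least 1 they were 91, 296, 113 (nano-SiO2+MT against control), 164, 55 and, for nano-SiO2 against MT, 272. With no filter they were 239 (nano-SiO2+MT against control), 229 (nano-SiO2+MT against nano-SiO2), 521 (nano-SiO2 against MT) and 766 (F test), lists numbered 7 in MT against control and 10 in nano-SiO2+MT against nano-SiO2, and shared genes 42 (nano-SiO2 and MT) and 188 (MT and nano-SiO2+MT). Without control 1 and nano-SiO2 2 they were 29, 119 (nano-SiO2+MT against nano-SiO2), 71 (interaction), 341 (nano-SiO2 against MT) and 632 (F test). With only the 2 groups in the fit they were 115, 53 and, for nano-SiO2 against MT, 364.

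Whether replicate numbers mark shared handling is not stated: the 18 same-number pairs correlated between -0.34 and 0.53, and 6 of 12 libraries had their best partner outside the group under the same number. As a block they gave 789 genes in nano-SiO2+MT against nano-SiO2 and 1578 in nano-SiO2 against MT, and moved no other number of genes by over 1.5 times. With the block, lists that had not passed did so for xylem in nano-SiO2+MT against control (0.00624), melatonin synthesis in MT against control (0.0345), pathogenesis-related genes in nano-SiO2+MT against MT (0.0322) and phenylpropanoids in the interaction (0.0424), and in nano-SiO2 against MT for senescence (0.0468), melatonin synthesis (0.0328) and sodium, potassium and proton transport (0.0446). Photosystem subunits in MT against control (0.0513) and clock genes in nano-SiO2+MT against nano-SiO2 (0.0547) no longer passed.

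Directions turned for the Calvin cycle list in nano-SiO2 against control (0.01 under quantile normalization, 0.06 without control 1 and nano-SiO2 2) and in nano-SiO2+MT against nano-SiO2 (-0.01), and for photosystem subunits in MT against control (-0.06, both quantile). Genes not called also turned: Glyma.09G062600 (-0.10 without control 1 and nano-SiO2 2, from 0.00 without nano-SiO2 2 to 0.24 with 1 library left out), Glyma.17G174500 (-0.05 quantile, 0.00 without nano-SiO2+MT 3 to 0.19), Glyma.06G147100 (-0.02 without nano-SiO2 3 to 0.55), Glyma.12G166200 (-0.11 without MT 3, -0.03 without nano-SiO2+MT 2, to 0.14) and Glyma.19G046800 (0.00 in 3 comparisons, since quantile normalization gives a top-ranked gene the same value in each library).

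With 1 library left out, the numbers of genes ran from 43 to 173 (nano-SiO2 against control), 350 to 1098 (MT against control), 60 to 470 (nano-SiO2+MT against control), 103 to 535 (nano-SiO2+MT against nano-SiO2), 34 to 98 (nano-SiO2+MT against MT), 88 to 213 (interaction), 227 to 977 (nano-SiO2 against MT) and 484 to 1080 (F test). Lists ran from 13 to 15, 10 to 14, 6 to 14, 11 to 17 and 5 to 13 in the 5 planned pairs. Correlations with the shared control ran from 0.35 to 0.49 (nano-SiO2 and MT), 0.22 to 0.48 (nano-SiO2 and nano-SiO2+MT) and 0.66 to 0.78 (MT and nano-SiO2+MT), and shared genes from 21 to 93, 10 to 45 and 52 to 359.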

Other observations

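The comparison of nano-SiO2 with MT and the left-out refits of its lists and of the interaction lists were chosen only after the data had been seen, and pathway counts were made on the annotation in the authors' deposited table. The asparagine synthetase genes Glyma.14G195000 and Glyma.02G228100 were far lower with nano-SiO2 than with MT (3.02 ± 2.68 against 112 ± 7.16 FPKM, n = 3, log2 change -5.01, limma adjusted p = 2.3e-05, and log2 change -4.72, adjusted p = 5.81e-07). Kunitz inhibitor Glyma.08G341700 (2.15 ± 0.421 against 26.3 ± 6.48 FPKM) and trypsin inhibitor A (Glyma.01G095232, 7.09 ± 2.68 against 40.2 ± 2.77 FPKM) fell by 3.10 and 2.40. GLOX1 (Glyma.04G026400) was higher with nano-SiO2 (log2 change 2.37, adjusted p = 2.88e-05), as were the vegetative storage protein Glyma.07G014500 (2.30, 0.000103), IRX15-LIKE, of xylan synthesis (Glyma.05G085700, 11.2 ± 3.76 against 1.59 ± 0.729 FPKM, 2.22, 0.0034), and fasciclin-like protein 11 (Glyma.03G180000, 1.68, 0.00324). These kept the call in every fit with 1 library left out. In all, 893 genes were called, 681 higher and 212 lower, around a median of 0.143 over all genes. Quantile normalization gave 341 higher and 343 lower, with a shift of -0.143, and median-ratio scaling 307 and 372, with -0.151. The number of genes was 490, 588, 305, 453, 227 and 285 without control 2, control 3, nano-SiO2 2, nano-SiO2 3, MT 1 and MT 2, and 341 without control 1 and nano-SiO2 2 together.

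In that comparison 16 lists passed the camera test, 8 up and 8 down, and only some are named. Among them were the photosystem, antenna and Calvin cycle lists (camera adjusted p = 2.48e-14, 7.28e-09 and 0.000959). Under quantile normalization these had 0.00605, 0.431 and 0.508, and the Calvin cycle list had 0.145 without MT 1. Called higher were 15 of 22 xylem and secondary wall genes, 20 when adjusted over the list alone (median 1.46, camera adjusted p = 2.48e-14; adjusted p = 0.509 with an estimated correlation). Of 72 phenylpropanoid genes 15 were higher, 29 higher and 1 lower when adjusted over the list alone (median 0.36, 4.13e-05; adjusted p = 0.509 with an estimated correlation). Of 91 pathogenesis-related genes 9 were higher and 2 lower, 16 and 4 when adjusted over the list alone (0.021; adjusted p = 0.674 with an estimated correlation; 0.0579 without nano-SiO2 3; 0.216 with no filter). The pathogenesis-related list also did not pass without MT 1. Of 54 heat shock genes 7 were higher, 12 higher and 1 lower when adjusted over the list alone (0.0155; adjusted p = 0.674 with an estimated correlation; 0.319 without nano-SiO2 3; 0.116 with no filter). This list also did not pass without nano-SiO2 1 or MT 3. Mean log2 values of the xylem list per library were 2.18, 2.59 and 2.74 in control, 2.58, 3.03 and 3.65 with nano-SiO2, 1.53, 1.77 and 1.66 with MT, and 1.59, 2.29 and 2.75 with both, while those of phloem markers ran from 2.05 to 2.25.

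Among other iron and copper genes, 2 were chosen for naming after their values were seen and were not refitted with libraries left out. The copper chaperone of superoxide dismutase (Glyma.05G055000) was at 57.7 ± 3.21 FPKM in control, 32.3 ± 0.83 with nano-SiO2, 14.9 ± 3.55 with MT and 42.8 ± 3.71 with both, and fell with MT (log2 change -1.91, adjusted p = 1.19e-05) and with nano-SiO2 (-0.82, 0.0313). The metal transporter DMT1 (Glyma.17G165200) rose with MT (log2 change 1.90, adjusted p = 0.000102) and with nano-SiO2 (1.07, 0.0243) but not with both (0.02, 0.985). The interaction terms of the chaperone and DMT1 were 2.30 (0.000103) and -2.95 (8.44e-05). Only some of the pathways that passed, among 130 on a background of 9846 genes, are named. Genes higher with nano-SiO2 than in control held 7 of 37 of linoleic acid metabolism (0.184 by chance, adjusted p = 5.79e-08). Genes lower with MT held 13 of 190 of phenylpropanoid synthesis (3.3 by chance, adjusted p = 0.00332) and 8 of 100 of flavonoid synthesis (1.74 by chance, adjusted p = 0.0146), although the flavonoid list did not pass the camera test there. Genes lower with both sprays than with nano-SiO2 held 10 of 100 of flavonoid synthesis (1.48 by chance, adjusted p = 0.000272).

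Further lists passed the camera test in nano-SiO2 against control. Auxin response genes lay lower (0 of 67 called, 1 higher and 5 lower when adjusted over the list alone; 1.85e-05; adjusted p = 0.598 with an estimated correlation), as did cell wall loosening genes (0 of 45 called, 2 higher and 8 lower when adjusted over the list alone; 0.000844; adjusted p = 0.708 with an estimated correlation). Without control 1 and nano-SiO2 2 neither passed (0.0502 and 0.124). Sugar transporters lay higher (1 of 46 by either adjustment, 0.00358; adjusted p = 0.82 with an estimated correlation), but not past the threshold without control 1 (0.0586), nano-SiO2 2 (0.197) or both (0.892), or with no filter (0.0678). Sodium, potassium and proton transport genes lay higher (1 of 110, 2 when adjusted over the list alone; 0.0118; adjusted p = 0.96 with an estimated correlation), but not without control 1 (0.207) or control 1 and nano-SiO2 2 (0.422). Photorespiration genes lay higher (0 of 37 by either adjustment, 0.0367; adjusted p = 0.749 with an estimated correlation), but not without control 2 (0.108), control 3 (0.115), nano-SiO2 3 (0.556) or nano-SiO2+MT 3 (0.0683), or under median-ratio scaling (0.0664).

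In MT against control, heat shock genes lay lower (4 lower and 1 higher of 54, 12 lower and 2 higher when adjusted over the list alone; 0.0181; adjusted p = 0.932 with an estimated correlation), but not without control 1 (0.135), MT 3 (0.113) or control 1 and nano-SiO2 2 (0.098), or with no filter (0.0875). In the combined spray against control, chlorophyll synthesis genes lay lower (1 higher and 1 lower of 43, 1 and 5 when adjusted over the list alone; 0.0075; adjusted p = 0.803 with an estimated correlation), but not without control 1 (0.685), nano-SiO2+MT 3 (0.0843) or control 1 and nano-SiO2 2 (0.626), or under median-ratio scaling (0.0703). Class III peroxidases lay lower (3 of 30 by either adjustment, 0.0103; adjusted p = 0.918 with an estimated correlation), but not without nano-SiO2+MT 1 (0.112) or with no filter (0.51). Ribosomal protein genes lay lower (0 of 258 by either adjustment, 1.26e-05; adjusted p = 0.92 with an estimated correlation), but not without control 1 (0.0658), nano-SiO2+MT 3 (0.136) or control 1 and nano-SiO2 2 (0.051). Vegetative storage proteins lay higher (2 of 5 by either adjustment, 9.9e-06; adjusted p = 0.166 with an estimated correlation). Melatonin synthesis genes lay lower (1 of 6, 3 when adjusted over the list alone; median -0.49, 0.0462; adjusted p = 0.738 with an estimated correlation), but not without control 1 (0.0605), nano-SiO2 1 (0.0539), nano-SiO2 2 (0.072), MT 3 (0.0624), nano-SiO2+MT 1 (0.0594), nano-SiO2+MT 2 (0.0606) or control 1 and nano-SiO2 2 (0.0923), or with no filter (0.165).

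In the combined spray against nano-SiO2, melatonin synthesis genes lay lower (2 of 6, 4 when adjusted over the list alone; 0.0369; adjusted p = 0.537 with an estimated correlation), but not without nano-SiO2 1 (0.0721), nano-SiO2 3 (0.0717) or nano-SiO2+MT 2 (0.0508), or with no filter (0.15). Cell wall loosening genes lay higher (3 higher and 1 lower of 45, 5 and 4 when adjusted over the list alone; 0.000182; adjusted p = 0.537 with an estimated correlation) and so did auxin genes (0 higher and 1 lower of 67, 1 and 1 when adjusted over the list alone; 3.19e-05; adjusted p = 0.537 with an estimated correlation), but not without nano-SiO2+MT 2 (0.0508 and 0.0657). Ribosomal protein genes lay above the other genes with a median of -0.02 (1 of 258 lower, 0 when adjusted over the list alone; 3.19e-05; adjusted p = 0.8 with an estimated correlation), but not without nano-SiO2 2 (0.549) or control 1 and nano-SiO2 2 (0.429). Glutathione transferases (0.0415), clock (0.0415), abscisic acid (0.0415), WRKY (0.0367) and ERF genes (0.0288) passed narrowly, with adjusted p = 0.8, 0.837, 0.432, 0.8 and 0.638 with an estimated correlation, and each lost the call without nano-SiO2 1 (0.401, 0.124, 0.0721, 0.236 and 0.111). The last 3 tests pointed up although their medians were -0.01, -0.07 and -0.11.

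In the combined spray against MT, senescence genes (0.0419) and nitrogen assimilation genes (0.0107) lay lower, and heat shock (0.0207) and cell wall loosening genes (0.0107) higher, each with adjusted p = 0.942 with an estimated correlation. Each lost the call without nano-SiO2+MT 2 (0.309, 0.217, 0.304 and 0.928). Lists that passed in none of the 5 planned pairs were those of C4-type carbon enzymes, starch synthesis, starch breakdown, sucrose metabolism, reactive oxygen scavenging, aquaporins, dehydrins with LEA and proline synthesis, pathogenesis-related genes (0.0322 in the combined spray against MT with the replicate number as a block), flavonoids, glycolysis with the TCA cycle, and flower and pollen. In MT against control their camera adjusted p-values in this order were 0.84, 0.717, 0.683, 0.656, 0.239, 0.446, 0.61, 0.245, 0.329, 0.792 and 0.409.

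For the interaction, further lists passed with positive terms for photosystem (0.000116), chlorophyll synthesis (8.91e-09), class III peroxidases (0.0425), auxin (3.13e-05), cell wall loosening (6.75e-05), ribosomal (2.43e-18) and dividing-cell genes (0.0169). Senescence (0.00794), glutathione transferase (0.011) and nitrogen genes (0.00153) passed with negative terms. In this order they had adjusted p = 0.564, 0.458, 0.787, 0.564, 0.564, 0.564, 0.771, 0.564, 0.787 and 0.787 with an estimated correlation. Of the 13 interaction lists past the threshold 8 stayed past it in all 12 fits with 1 library left out. The photosystem (0.0798 without control 1), senescence (0.159 without MT 1), peroxidase (0.164 without nano-SiO2+MT 2), glutathione transferase (0.302 without MT 3) and dividing-cell lists (0.334 without nano-SiO2 2) did not. With no filter the dividing-cell list had 0.195, and under quantile normalization the peroxidases had 0.109.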
